A study of Arabidopsis thaliana with 3 samples.

How the data were processed

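Gene expression in Arabidopsis thaliana inflorescences was measured on 3 two-colour cDNA arrays, on which spotted cDNA elements are hybridised with 2 labelled RNA sources at once and each element gives the ratio of the 2. Every array carried total RNA of wild-type inflorescences in channel 1 and of apetala2 inflorescences in channel 2, per the labels. The labels number the arrays as sets 1 to 3, and these numbers are used here as arrays 1 to 3. Nothing in the labels says whether the sets came from separate plants or whether the same wild-type RNA was used on each. Nor do the labels say whether a column combines more than 1 hybridisation. The p-values therefore rest only on spread between these 3 columns, which may be technical and is largely pooled across elements.

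The deposited values, taken here as log2 ratios of the 2 channels (a reading of the values and not of the labels), were preprocessed and normalized by the authors before deposit. The labels say so, refer to an earlier publication and give no steps. The scanner, background correction, spot filter, normalization method, dye of each source and log base are not given in the sources used here. The unit was read from the values: multiplied by the natural logarithm of 2, 98.42% of the 27939 values fell within 0.02 steps of a multiple of 0.0001, against 4% by chance and 3.92% for base 10. Natural-log ratios of 4 decimals converted to base 2 would lie on such a grid. All 27939 values ended in the digit 3, which does not affect any ratio or mean at the precision printed. A 0 given that digit would read as a small positive value. GP002F7, for example, read 0 at 4 decimals on array 2 and was counted as having the same sign on all arrays. Counts of elements with the same sign on all arrays may include such cases. The table held 9313 elements with a value on each array, no missing value and no exact 0.

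Neither the dye of each source nor the numerator of the ratio is given in the sources used here. The 2 sides of the comparison are therefore called positive and negative, as the deposited values have them, and no statement says which genotype had more of a transcript. Elements are named by IDs such as GP034E6. These were read as a plate number (3 digits), a row letter (8 letters) and a well column (1 to 12), a reading of their form that no source states. None of the IDs occurs in the RefSeq gene table used here (assembly TAIR10.1; 0 matches), so no element could be tied to a gene. As a result, the value of the AP2 transcript, the 10 gene lists (229 entries) and the 20 annotation classes fixed before the data were examined could not be computed, and counts are of array elements, of which several may represent 1 gene.

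The main test was fixed before the data were examined: limma 3.58.1 in R 4.3.3 (lmFit and eBayes) of each element's mean log2 ratio over the 3 arrays against 0, two-sided, with Benjamini-Hochberg adjustment over the 9313 elements and a threshold of 0.05. Values were used as deposited, with no further centring, filter or pseudocount. The moderated variance had 23.8 prior degrees of freedom and a prior SD of 0.34. Agreement between arrays was described with Pearson and Spearman correlations across elements, which are not independent replicates. The rule for named genes required 1 gene per element and so named none. The 2 called elements with the largest mean on each side and 1 sign on all arrays are given by ID in their place, a choice made after their values were seen. The number of arrays limits the precision.

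The test was run on simulated ratios of 9313 elements on 3 arrays, with the fitted variance distribution and 200 changed elements of each size. It called 35.5% of elements changed by 0.5 on the log2 scale, 96.0% of those changed by 1 and 100% of those changed by 2. None of these had the wrong sign, and 5.89% of its calls were false. These shares hold for that setting only. Fewer elements were changed there than were called in the data, which makes the adjusted threshold stricter. The simulated noise was also independent between arrays and centred on 0.

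Alternatives fixed beforehand were centring on the array median, scaling the arrays to 1 spread, an array minimum of 2, robust eBayes, array weights, a one-sample statistic without a shared spread, a threshold of 0.01, a 2-fold minimum, limma's treat against 1.2-fold and leaving out each array. Centring on the array mode (the peak of a kernel density of bandwidth 0.1), its separate parts (lowering all arrays alike by the mean of the modes, and making the modes equal with their mean kept), and centring on plate medians and on row-letter medians were added after the data were seen. Gaussian mixtures and density-based clumps (scikit-learn 1.9.0, Python 3.11.15) served as descriptions only.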

Results

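Transcript levels were compared between wild-type and apetala2 inflorescences of Arabidopsis thaliana on 3 cDNA arrays, each a direct hybridisation of the 2 sources. APETALA2 is a transcription factor required for the identity of sepals and petals, and its loss alters the organs that form in the flower. The comparison asks which transcripts differ in abundance between mutant and wild-type inflorescences. Each array gave a log2 ratio for 9313 cDNA elements. The deposited sign could not be tied to a genotype, so values are reported as positive or negative.

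The 3 arrays had medians close to 0 and differed in spread. The median log2 ratio was 0.03 on array 1, -0.02 on array 2 and 0.05 on array 3. The median absolute deviation (scaled to an SD) was 0.55 on array 1, 0.37 on array 2 and 0.61 on array 3. Ratios ran from -4.89 to 2.93 on array 1, from -4.30 to 1.96 on array 2 and from -3.66 to 2.65 on array 3. A ratio below -1 was found for 1074 elements on array 1, 251 on array 2 and 956 on array 3, and a ratio above 1 for 211, 128 and 225 elements, respectively.

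The arrays ran in the same direction. Across elements, Pearson's r was 0.784 between arrays 1 and 2, 0.697 between arrays 1 and 3 and 0.677 between arrays 2 and 3, with Spearman's rho of 0.676, 0.608 and 0.589. No 2 arrays held identical values. All 3 arrays gave the same sign for 5485 elements, or 58.9% of the total, where independent signs would give 25%. The median SD of an element over the 3 arrays was 0.28.

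**Figure D1:**
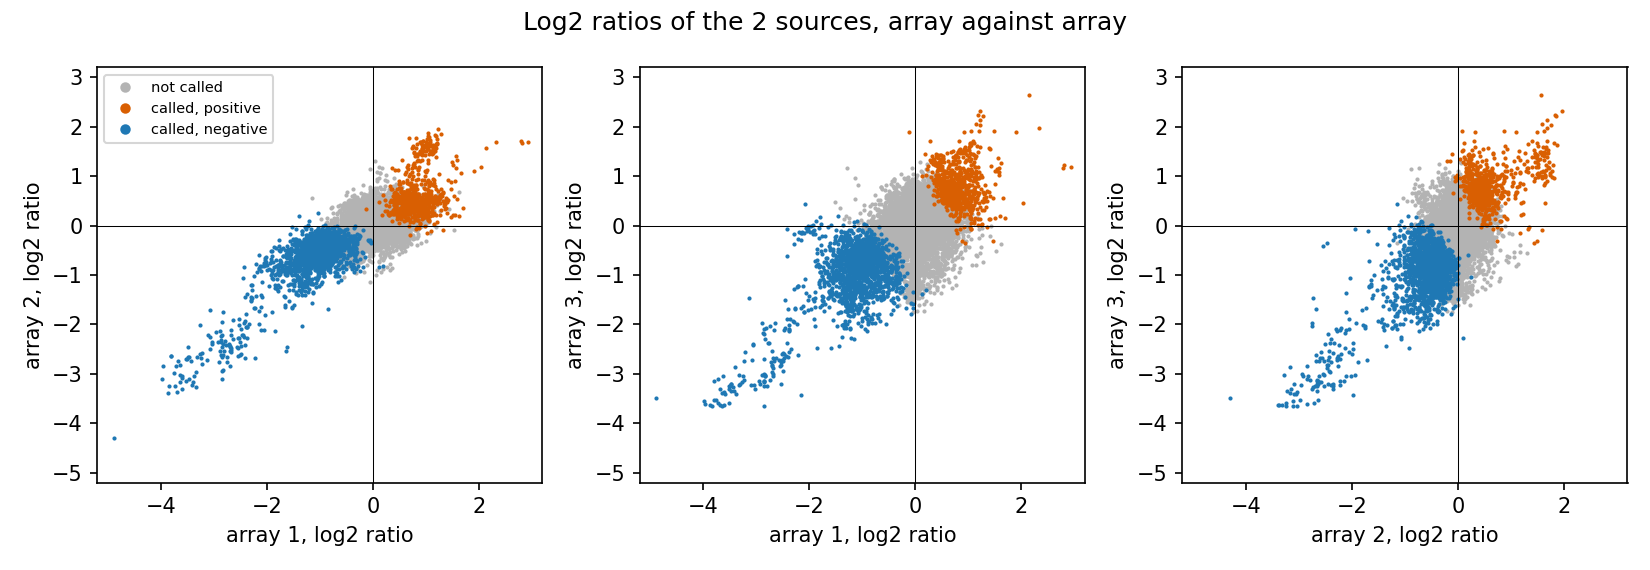
Log2 ratios of 9313 elements on each pair of arrays; each point is an element, coloured by its call in limma at an adjusted p of 0.05 (grey, not called; orange, positive; blue, negative). The points follow the diagonal, with r between 0.677 and 0.784, and the negative side reaches farther from 0 than the positive side.

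Of the 9313 elements, 2493 (26.8%) differed between the 2 sources in limma's test at a Benjamini-Hochberg adjusted p of 0.05. The sources used here do not say whether dyes were swapped, and a dye effect of an element that repeats on all 3 arrays would be called in the same way as a difference between the sources. Negative ratios made up 1795 of these, or 72.0%, and positive ratios 698. The median mean log2 ratio was -0.81 among negative calls, a 1.76-fold difference, and 0.65 among positive calls, a 1.57-fold difference. All 3 arrays shared the sign for 2453 of the called elements and not for the other 40. The remaining 6820 elements did not pass. The smallest absolute mean of a call was 0.50 on either side, which leaves room for changes of about that size among them. A one-sample t statistic without a spread shared across elements called 0 elements on either side after adjustment. The count of 2493 thus rests on limma's shared variance. With 3 arrays that t statistic has little power after adjustment over 9313 elements, so 0 calls were likely even where the sources differ. Of the arrays left out singly, array 1 lowered the count most: without it 853 elements were called, 182 of them positive and 671 negative. The shared variance was estimated anew from the 2 arrays left, so this fall does not measure the weight of array 1 alone. Without array 2 the positive calls numbered 352. With the arrays centred on their modes, which lay at 0.15, 0.03 and 0.32, the count was 2097, of which 90.3% were negative, against 72.0% as deposited. That centring moved the median of the means from 0.04 to -0.13.

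The differences of larger size lay mostly on the negative side. A mean ratio beyond 2-fold was found for 483 negative and 109 positive elements, and every one of them passed the test. Of the 109 positive elements, 63 belonged to 1 group with similar ratios, described below, and may not be separate differences. Between elements of that group the SD was 0.12 on arrays 1 and 2 and 0.24 on array 3, so array 3 ratios were shared less closely. Beyond 4-fold there were 108 negative elements and 1 positive element. The 5th and 95th percentiles of the mean ratio were -1.01 and 0.60, and the 1st and 99th percentiles were -2.37 and 1.12. The number of elements did not fall steadily toward the negative end. It was 40 for a mean between -2 and -1.5 and 25 between -2.5 and -2. It was then 48 between -3 and -2.5, and 35 in the open range at -3 or below. A group of 19 elements with nearly 1 set of 3 ratios, described below, lay around a mean of -2.59. The elements below -2 came from 59 of the 114 plate numbers.

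The element GP058G5 had the lowest mean log2 ratio, -4.22 ± 0.70 (SD, n = 3), an 18.7-fold difference with an adjusted p of 3.44e-13 in limma. Its standard error in limma was 0.22, which draws on the variance shared across elements. That is smaller than its 3 values alone would give. GP059G6 followed at -3.63 ± 0.24 (SD, n = 3), a 12.4-fold difference, also at an adjusted p of 3.44e-13 in limma. On the positive side, GP034E6 had the highest mean, 2.12 ± 0.54 (SD, n = 3), a 4.34-fold difference with an adjusted p of 1.06e-08 in limma. GP032C8 had a mean of 1.99 ± 0.32 (SD, n = 3), a 3.99-fold difference, with an adjusted p of 1.05e-08 in limma. The table does not pair these IDs with genes.

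**Figure D2:**
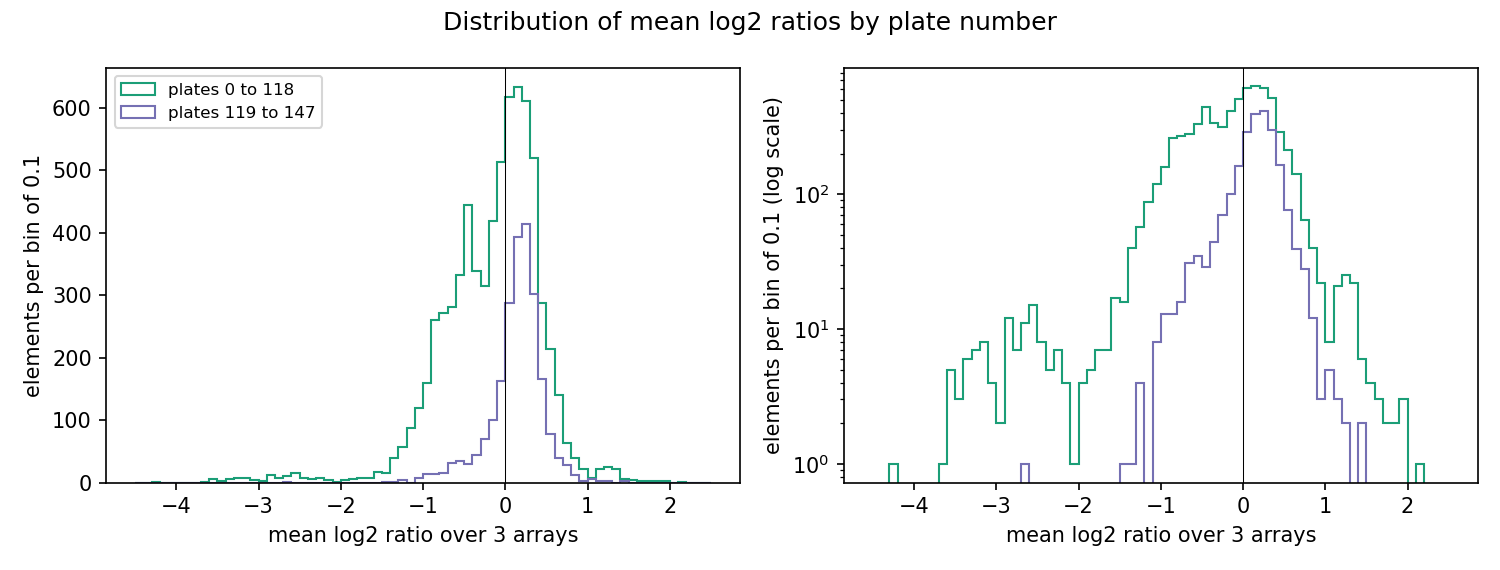
Number of elements per bin of 0.1 of the mean log2 ratio over the 3 arrays, on a linear axis (left) and a log axis (right), for elements of plate numbers 0 to 118 and 119 to 147. The lower plates show a shoulder on the negative side, and 107 of their elements lie below -2, against 1 of the higher plates.

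The share of negative calls differed with the plate number read from the IDs. On plate numbers 0 to 118, 1680 of 7051 elements (23.8%) were called negative, with an exact 95% binomial interval of 22.8% to 24.8%, which covers counting error only. These plates were not uniform. Negative calls made up 18.7% on plates 0 to 11 (16.0% to 21.6%), 13.3% on plates 32 to 45 (10.8% to 16.2%) and 25.8% on plates 55 to 118 (24.6% to 26.9%), and positive calls 13.8%, 6.09% and 7.05%. On plate numbers 119 to 147, 115 of 2262 (5.08%) were called negative, with an interval of 4.22% to 6.07%. With each plate centred on its median, an alternative added after the data were seen, the shares were 17.1% on the lower and 6.94% on the higher plates, and the difference fell from 18.7 to 10.2 percentage points. Positive calls made up 7.72% of the lower and 6.81% of the higher plates, with intervals of 7.10% to 8.36% and 5.80% to 7.93%. A mean above 1 was found for 97 of 7051 elements on the lower plates and 12 of 2262 on the higher plates, a smaller share. The quartiles of the mean were -0.50 and 0.24 on the lower plates and 0.02 and 0.32 on the higher plates. The higher plates thus had a narrower spread between the quartiles. The group of 63 elements described below all had a mean above 1, and only 1 of them lay on the higher plates. The smaller share of means above 1 on the higher plates thus rests on that group. Apart from it, the counts above 1 show no clear difference between the plate ranges. The median mean log2 ratio was -0.05 on the lower plates and 0.18 on the higher plates. It was above 0 on each of the 29 higher plates and on 20 of the 85 lower plates. The higher plates had positive medians on every array, 0.16, 0.04 and 0.34 on arrays 1, 2 and 3. The division was chosen after the values were seen, as the one with the largest chi-square statistic for negative calls among all divisions by plate number. Plate number accounted for 7.79% of the variance of the mean ratio between elements.

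**Figure D3:**
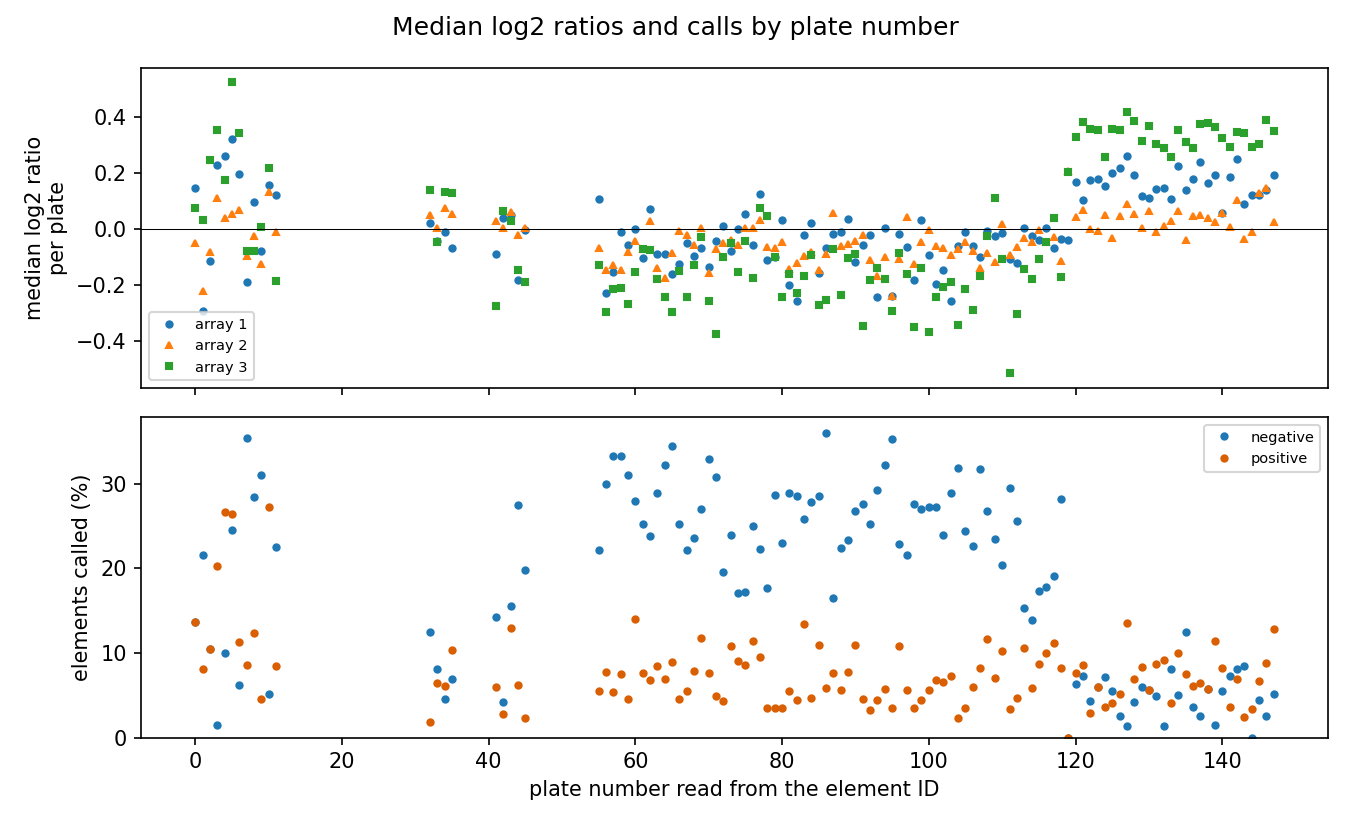
Median log2 ratio of each plate on each array (top) and the percentage of its elements called positive or negative (bottom) against the plate number read from the element ID; each point is 1 plate, with 22 to 94 elements. Plates 119 to 147 had between 0 and 12.5% negative calls, and the lower plates between 1.45% and 36.0%.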

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

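Leaving out 1 array gave between 853 and 2301 calls, between 182 and 652 positive and between 671 and 1649 negative, where 2 arrays share the spread across elements. A one-sample statistic with no shared spread called 0 elements on either side after adjustment (1788 at an unadjusted p under 0.05, against 3533 in limma). The calls thus rest on the variance shared across elements. That one-sample statistic has little power on so few arrays, so its 0 calls are not evidence that the elements do not differ. At an adjusted p of 0.01 there were 1537 calls, 283 of them positive. With a 2-fold minimum there were 592 (109 positive, 483 negative), and with treat against 1.2-fold 1141 (195 positive, 946 negative); these counts fall by construction. Centring on the array mode, added after the data were seen as were its parts, left 204 positive calls. Lowering all arrays alike by 0.17, the mean of the modes, gave 2915 calls (311 positive, 2604 negative), and making the modes equal with their mean kept gave 1514 (368 positive, 1146 negative), so both parts lower the positive count and they move the negative count of 1795 in opposite directions. Negative calls outnumbered positive ones wherever any were made, from 66.1% of calls with plate centring to 90.3% with mode centring. Without the 1% of elements with the largest means, r fell to 0.632 between arrays 1 and 3 and to 0.594 between arrays 2 and 3. Centring on array medians (2207 calls), scaling (2548), robust eBayes (2643), array weights (2496), plate centring (2064) and row centring (2407) kept the total within 1.5 times of 2493, and an array minimum of 2 removed nothing. The 4 named elements kept their sign and call in all 32 values under centring, scaling and left-out arrays, with adjusted p up to 0.000817 in limma. They had been chosen for the largest means, so this says nothing about smaller calls. No paired analysis was possible because there is 1 group of arrays and each array already pairs the 2 sources. Gene-level means, the gene list tests and the AP2 value were not run, since no element could be named. Signal over background was not given, so the depth of single ratios is unknown.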

Other observations

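The tests in this part were chosen after the data were seen, except that the outcomes expected of plate centring, row centring and the spread between arrays were set down before those values were computed.

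With the sign of 1 array turned, limma called 0 elements for each of the 3 arrays, with 12, 16 and 53 elements at an unadjusted p under 0.05. The deposited signs, with 2493 calls, were the 1 of 4 sign settings with as many calls, and the highest other setting gave 0. With 4 settings the share cannot fall under 0.05.

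The mean ratios of plates 0 to 118 were described better by 3 Gaussian components than by 1 (Bayesian information criterion 11792 against 13154). The components had centres of 0.15, -0.62 and -2.62 and held 64.1%, 34.1% and 1.82% of the elements. On plates 119 to 147 the criterion was lowest for 2 components, with 78.8% of elements at 0.20 and a broad remainder at -0.11.

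The share of negative calls was 18.7 percentage points higher on plates 0 to 118 than on plates 119 to 147. Within each of the 8 row letters it was between 14.6 and 21.3 points, with the lowest bound of the 95% bootstrap intervals over plates at 10.3 points, where an offset of well rows shared by all plates forbids a difference. These differences within rows argue against such an offset as the cause. Centring each row letter left 18.9 points (17.0 to 20.6). It moves both plate ranges nearly alike and so could not have decided the question. Centring each plate lowered the difference to 10.2 points (95% bootstrap interval over plates 8.51 to 11.7). That is above the 5 points expected beforehand if offsets were the whole cause but not clear of the 10 points expected if they were not. Reading this as excluding offsets as the whole cause was decided after the value was seen. A constant offset of each plate may account for part of the difference, but the fall cannot show that it does. A plate's median is itself lower where more of its elements are negative, so centring shrinks the difference without any offset too. Elements of plates 119 to 147 had a median SD over arrays 0.858 times that of the lower plates (0.827 to 0.894). This argues against a loss of calls through a larger spread between arrays. The arrays differ in spread, so the SD also grows with the size of a ratio and is not a measure of noise alone. A dye or brightness trend left by the normalization stays open, because the table used here holds 0 columns of brightness, and so does a different choice of genes on the 2 sets of plates, which is the untested biological explanation.

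Some elements shared nearly 1 set of 3 ratios. With a radius of 0.2 and at least 8 neighbours, 130 elements fell into 6 groups apart from the main cloud. The largest held 63 elements, all called positive and with a mean above 1, around 0.999, 1.57 and 1.27 on arrays 1, 2 and 3. Its SDs between elements were 0.12, 0.12 and 0.24, so its ratios were less alike on array 3. A group of 20 elements, all called negative, lay around -2.02, -0.77 and -0.10, with SDs between elements of 0.11, 0.12 and 0.07. A group of 19 elements, also all called negative, lay around -2.58, -2.42 and -2.76. Another 8 lay around 0.13, 1.01 and -0.65 and were not called. Nearly all grouped elements lay on plates 0 to 118, which hold 7051 of the 9313 elements. On plates 119 to 147 there was 1 element of the group of 63, 1 of the group of 19 and 0 of the others.

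Chance density of the cloud, neighbouring positions on the plates and several copies of one transcript are possible explanations of these groups. Among the 257 elements with a mean above 1 or below -1.5, 497 pairs lay within 0.2 of each other, against at most 245 in 100 draws in which the ratios were jittered with an SD of 0.2. This decides nothing about chance density: the jitter is wider than the SDs within the largest group on arrays 1 and 2 (0.12 on each) and so loosens any tight set, and the 257 elements include all 63 of that group, which prompted the test. Chance density stays open for all 6 groups. The number of elements in groups also depended on the radius, with 119 at 0.12, 72 at 0.15 and 130 at 0.2. Of the 6 groups, 0 lay on fewer plates than the central 95% of random sets of their size (44 plates for the largest, against 43 to 54) and 1 pair of their elements lay in adjacent wells, which argues against neighbouring positions for these groups, and copies of 1 transcript stay a hypothesis, since 0 element IDs could be matched to a gene.

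On plates 0 to 11, adjacent wells of a row shared ratios more often than shuffled ones: 63 of 590 adjacent pairs lay within 0.2 of each other on the 3 arrays, against a median of 12 and at most 20 in 100 shuffles of the elements within plates. On the other plates it was 118 of 6907 pairs, against a median of 119.5 in the shuffles, of which 56 held as many.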
